A study of Homo sapiens with 4 samples.

How the data were processed

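RNA of BE(2)C neuroblastoma cells with a doxycycline-inducible miR-204 construct was measured on 4 one-colour (Cy3) 60-mer expression arrays of 1 design, annotated on hg19, on 1 slide and in 1 scan. The labels give 2 arrays without doxycycline (DMSO vehicle) and 2 with it, 48 hours after addition. Per the file headers, the scanner files hold fluorescence intensity from Feature Extraction 10.7.3.1, background-subtracted and detrended within each array, with a surrogate value where a spot did not exceed background. They are not normalized between arrays. The deposited value table is in log2, per the authors made with limma, whose version and settings are not stated. Its column medians, between 6.03 and 6.09, show that it was normalized between arrays. The unit was read from the values. Spots flagged as outliers were left out, 57 to 99 per array, and the spots of one probe were averaged.

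By the scanner files' labels, the median processed signal was 33.0, 48.7, 36.1 and 36.4 intensity units on no dox 1, no dox 2, dox 1 and dox 2. In the same order, the 75th percentile was 203, 290, 229 and 226. Surrogate values made up 16.1%, 9.34%, 18.2% and 14.9% of spots. Signal over background limits what can be measured: a probe not well above background on an array gives only an upper limit there. For genes not well above background on either array of one group, the fold is given as a bound. It was computed against the array's lowest level of a probe well above background, or the gene's own level where that was higher. Such a bound allows for no measurement error. Where the gene's own level was the higher one on both arrays, the bound equals the plain estimate.

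Each scanner file's group label and each table column's label come from the same sample record, yet the values of 2 records are exchanged between the sources. Because nothing deposited settles the assignment, both accounts were analysed. The scanner labels were the design fixed before the data were examined, as were the named gene rule, the lists, the tests and the alternatives for that account. The value table was among those alternatives. The full account by the value table, with its own alternatives, was chosen after seeing the data.

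For the scanner labels, log2 of the processed intensity minus each array's own 75th percentile over non-control probes was used. For the value table, the authors' log2 values were used as deposited, with the background flags of the scanner array that each column matched. Probes were kept if well above background on both arrays of at least 1 group. Each gene was represented by its kept probe with the highest mean. Names came from the symbol in 31116 probes, an accession in 3343, a synonym in 496, a description in 11, and the file's own name in 23235, giving 43395 names. The reference supplied names only; coordinates are those of the array files. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The tables were prepared in Python 3.11.15 with pandas 2.3.3, and drawn with matplotlib 3.10.9.

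The 30 gene lists named 791 genes, of which 785 were on the array. They covered reported miR-204 or miR-211 targets, MYC/MYCN-activated and MYCN-repressed genes, ribosome biogenesis, cell cycle, histones, neuroblastoma identity, catecholamine synthesis, neuronal genes, axon guidance, apoptosis, stress responses, mitochondrial genes, metabolism, autophagy, interferon, immediate early, TGF-beta, the microRNA pathway and markers of 4 other cell types. Lists with at least 5 kept genes were tested with limma's camera at a preset inter-gene correlation of 0.01. Beside it stood camera with an estimated correlation and fry, which tests whether a list moves one way. Fry's lowest adjusted p was 0.147 by the scanner labels and 0.593 by the value table.

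Named are MYCN, TRPM3 and any probe of the microRNA. Also named are the 12 largest increases and decreases among genes past the threshold, with both arrays of a group on one side, well above background and unsaturated on all 4 arrays, leaving out names that are not symbols. Up to 4 bounds per direction follow, then per list up to 4 members past the threshold or, where none passed, 2 with the smallest p. If no gene passed, the 10 with the smallest p in each direction are given. The result of 1 list and those of 3 members of other lists are not printed, although the rule names them. FOS and EGR1 by the value table and RAB22A and SIX3 by the scanner labels were added after their values were seen, to give both accounts.

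The alternatives were normexp background correction (offset 50), quantile normalization or median scaling, no filter or a stricter filter on dim probes, the mean over a gene's probes, every probe on its own, an intensity trend with robust eBayes, replicate number as a term, adjusted p thresholds of 0.1 and 0.01, and each array left out in turn. For the value table the alternatives also included scanner values in its assignment, and leaving out probes that hold the stretch TCTCCC. A planned test of 3' UTR sites for the miR-204 seed was not run, because no 3' UTR sequences were at hand.

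The fits were tested on simulated data of the same size and spread, with 200 changed genes each. Of 2-fold, 4-fold and 16-fold changes, 0%, 64.3% and 90% were recovered in the scanner account, with 9 false calls. In the value table's account 85.7%, 95.7% and 100% were recovered, with 12 false calls. A list shifted by 0.5 log2 was called in both, with 0 and 1 other lists called.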

Results

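BE(2)C is a human neuroblastoma cell line with MYCN amplification, and the cells used here carried a stable miR-204 construct that doxycycline switches on. Total RNA was collected 48 hours after doxycycline, given in the labels as 1 mg/ml, a unit that nothing else in the data checks, or after the DMSO vehicle. The data were 4 one-colour expression arrays, 2 without doxycycline (no dox) and 2 with it (dox), all read on 1 slide in 1 scan. Each array held 60901 non-control spots for 58201 probes, and no spot was saturated. By the scanner files' labels, the share of spots well above background was 69.0% and 77.9% on no dox arrays 1 and 2. It was 66.3% and 70.0% on dox arrays 1 and 2. By the deposited value table, the array at 77.9% is dox 1 and that at 66.3% is no dox 2, as given below. With 2 arrays per group, the number of arrays limits the precision. The labels number the replicates but do not say that they were separate cultures, so each p-value measures only the spread between these samples.

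The deposited data gave 2 different accounts of which array was which. Each of the 4 columns of the deposited value table was compared with each of the 4 scanner files over 36562 probes well above background on all arrays, after centring each probe on its mean. No dox 1 and dox 2 matched the scanner file of the same name, at r = 0.921 and 0.916 across probes, which are not independent replicates. The no dox 2 column matched the dox 1 scanner file at r = 0.918, against -0.51 with its own. The dox 1 column matched the no dox 2 scanner file at r = 0.905, against -0.521 with its own. So 2 of the 4 arrays carried exchanged groups between the sources, and nothing else deposited settled which was right. By the scanner files the no dox arrays lay in slide row 1 and the dox arrays in row 2; by the value table the groups lay in slide columns 1 and 2. Group and slide position therefore could not be told apart in either account. The gene and list tests were run by both accounts: the scanner files' labels, which were chosen as the source before the data were examined, and the value table's columns. Most single genes are given in the account where they were selected.

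**Figure D1:**
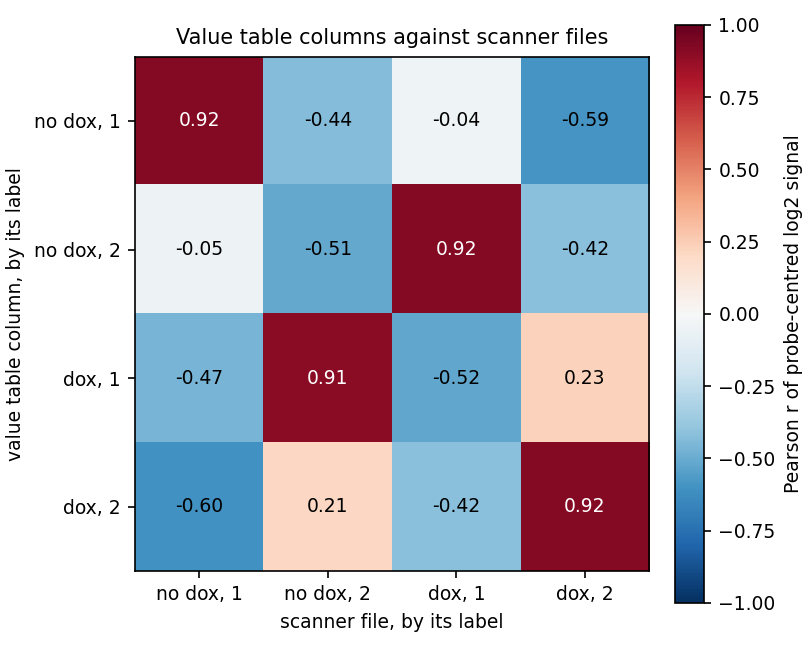
Pearson correlation across 36562 probes, on log2 values centred per probe, between each column of the deposited value table (rows) and each scanner file (columns). No dox 1 and dox 2 match their own scanner files (0.921 and 0.916), while no dox 2 and dox 1 match each other's (0.918 and 0.905).

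The series title concerns miR-204 and MYCN, the transcription factor gene amplified in this line. The comparison asks how transcript levels differ when doxycycline is given to induce the microRNA. No doxycycline-treated cells without the construct were included, so effects of doxycycline itself cannot be told apart from those of miR-204. The level of MYCN hardly differed between the 4 arrays. The scanner values ranged over 0.13 log2 from the lowest array to the highest and the table's values over 0.10 log2, so with these scalings no assignment of these arrays to groups gives a larger difference. MYCN averaged by the scanner labels 8.09 ± 0.092 log2 without and 8.08 ± 0.021 log2 with doxycycline, above each array's 75th percentile (SD, 2 arrays each). The difference was -0.011 log2 with a standard error of 0.10 (adjusted p = 0.996, limma). In the value table it averaged 15.33 ± 0.031 without and 15.33 ± 0.072 with doxycycline on the authors' log2 scale, a difference of -0.004 with a standard error of 0.087 (adjusted p = 0.998, limma). Both signs turned under some of the alternative settings, as did that of TRPM3, within a range from -0.11 to 0.05 log2 for MYCN over all alternatives. The MYCN value came from 1 probe, at chromosome 2, 16086767 to 16086826 (hg19). TRPM3, the gene whose intron holds miR-204, differed by 0.012 log2 by the scanner labels and by -0.02 by the value table (adjusted p = 0.995 and 0.98, limma), read from its brightest probe. Its other 2 probes were at -0.28 and -0.16 by the scanner labels and at 0.075 and 0.057 by the value table, with adjusted p of at least 0.856. The array had 0 probes for miR-204 or its relative miR-211, so induction itself could not be read from these data.

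No gene passed the test by the scanner labels. Of 31062 genes, 0 had an adjusted p below 0.05 in limma, and 1929 had an unadjusted p below 0.05, of which 480 were higher and 1449 lower with doxycycline. The lowest adjusted p was 0.599. On simulated values of the same spread, 0% of 2-fold changes and 64.3% of 4-fold changes were recovered, so changes near 2-fold were not detectable here.

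The genes with the smallest p-values in each direction are given as values that did not pass, all with an adjusted p of 0.599 in limma. A bound among them allows for no measurement error and establishes no change. On the higher side were OR6P1, an olfactory receptor gene, at 1.15 log2, GDF2, which encodes BMP9, at 1.02, and LYNX1, a modulator of nicotinic receptors, at 0.86. FAM222B was at 1.48, and 4 non-coding genes were at 1.61 (MIR940), 1.46 (AHI1-DT), 0.96 (LINC02082) and 0.82 (PCGF3-AS1). The remaining pair, LINC00640 and TEX13C, were not well above background without doxycycline, so their values are bounds, at least 2.8-fold and at least 1.94-fold higher. On the lower side only FLJ39095, at -1.17, was well above background on all 4 arrays. The others were not well above background with doxycycline. Their bounds were at least 2.11-fold lower for EPCAM, the epithelial adhesion gene, at least 1.75-fold for C6orf58, 1.58-fold for KBTBD12, 1.49-fold for DEFB119, a defensin gene, and 1.41-fold for PDE6H. COL15A1 and ETV3L were at least 1.33-fold lower, ZNF350-AS1 at least 1.26-fold and NMRK1 at least 1.12-fold. In the value table MIR940, FAM222B, LYNX1, LINC02082 and FLJ39095 had the opposite sign, between -0.19 and 0.06 log2.

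By the value table's columns, 549 of 31366 genes passed, 489 higher and 60 lower with doxycycline (adjusted p below 0.05, limma). Most of the genes that rose were not annotated as mRNA: 146 had an mRNA accession and 343 did not. Genes with an mRNA accession made up 29.9% of those that rose and 49% of all genes tested. In each of the 549, both dox arrays lay on the same side of both no dox arrays, and 267 differed at least 2-fold, 252 of them higher. The median absolute change was 0.99 log2. The balance moved when 1 array was left out: 502 genes passed as higher and 216 as lower without no dox replicate 1, and 881 and 83 without no dox replicate 2. Without dox replicate 1 these counts were 454 and 30, and without dox replicate 2 they were 406 and 27. In all, 273 genes passed when the scanner values scaled to the 75th percentile were put in the table's assignment, of which 201 were among the 549.

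The 12 largest increases were in genes of varied function. TMCO2, which encodes a transmembrane protein, rose by 2.18 log2 with a standard error of 0.14 (adjusted p = 0.00233, limma). TRPV5, an epithelial calcium channel gene, rose by 2.02, and ANO7, an anoctamin family gene, by 1.96, the latter with the lowest adjusted p of 0.00117. RSPO3, a secreted activator of Wnt signalling, rose by 1.89, CEP85, a centrosomal protein gene, by 1.83, MFAP5, a microfibril component, by 1.81, MCEMP1, a mast cell membrane protein gene, by 1.80 and EPS8L3 by 1.79. The other 4 were non-coding, at 1.89 (GLIS2-AS1), 1.84 (LINC00842), 1.82 (ACTA2-AS1) and 1.79 (SSBP3-AS1). Of these 12, only ANO7 and LINC00842 had other probes to compare, and those did not rise, as given below. Across these 12 genes the adjusted p ran up to 0.0217. The largest bounds for transcripts not well above background without doxycycline were 2.31-fold for ENST00000503685, 1.92-fold for lnc-C2orf49-2, 1.91-fold for lnc-FRG1-4 and 1.9-fold for lnc-AL353597.1-2. Apart from that of lnc-FRG1-4, these bounds equal the plain estimates.

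The decreases were smaller. ABCC8, the sulfonylurea receptor subunit of the potassium channel of beta cells, fell by 1.30 log2 with a standard error of 0.098 (adjusted p = 0.00315, limma), and SHOX, a homeobox gene of limb growth, fell by 1.23. LYZL1, a lysozyme-like gene, fell by 1.15, LRRC8E, a volume-regulated anion channel subunit, by 1.06, SLC67A1 by 1.02, and ZAN, the sperm zonadhesin gene, by 1.02. CHIA, an acidic chitinase, fell by 0.94 and CST2, a salivary cystatin, by 0.90. The non-coding genes CCDC13-AS1, EPCIP-AS1, HM13-AS1 and TUNAR fell by 1.19, 1.12, 0.97 and 0.96. Of these 12, only ZAN and TUNAR had other probes to compare, and those did not fall, as given below. Across these 12 genes the highest adjusted p was 0.0462. In the 1 case of a transcript that passed and was not well above background with doxycycline, ENST00000424493, the bound was 1.41-fold lower. This bound equals the plain estimate.

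For 70 of the 549 genes, another probe that shared no 20-base stretch with the called one was well above background on all 4 arrays. These other probes had a median of 0.011 log2 in the called direction, against 1.06 for the called probes of the same genes, and 40 of the 70 pointed in the called direction. For ANO7, LINC00842, TUNAR and ZAN, which had such a probe, the other probes stood at -0.025, -0.139, -0.05 and -0.423 log2 in the called direction. Without probes that hold the stretch TCTCCC, these 4 genes were read by another probe. With doxycycline they were then at -0.12, -0.139, 0.05 and 0.423 log2. The changes of these 4 are thus changes of single probes. Of the 549 genes, 479 had no other such probe to compare, RAB22A and SIX3 among them.

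**Figure D2:**
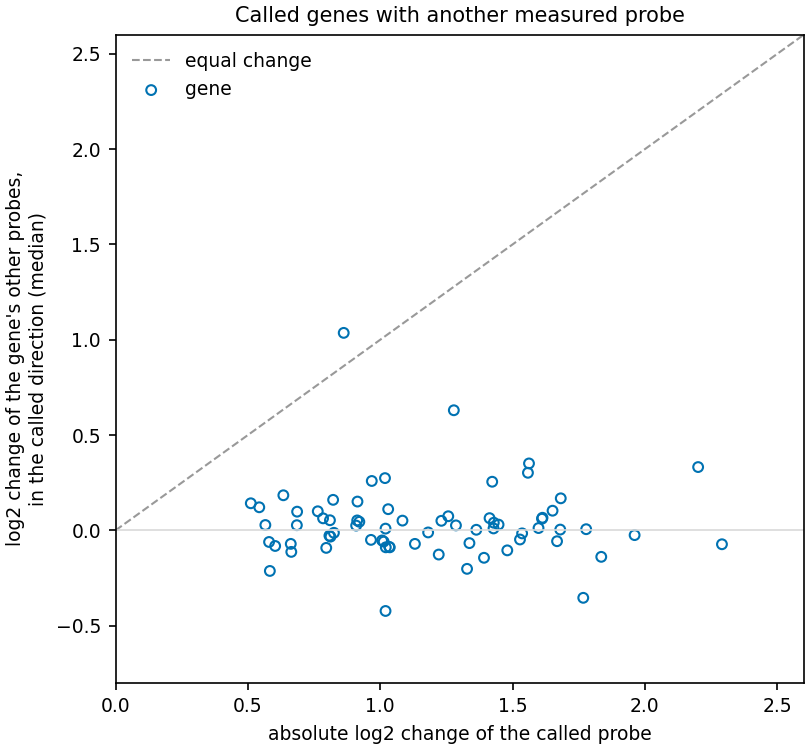
Each point is 1 of the 70 genes called by the value table's columns that had another measured probe: the absolute log2 change of the called probe (horizontal) against the log2 change of the other probes, counted positive in the called direction (vertical). The called probes have a median of 1.06 log2 and the other probes of 0.011 log2.

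Among genes reported elsewhere as miR-204 or miR-211 targets, 1 of the 31 measured passed by the value table and 0 by the scanner labels. Over all genes, 549 of 31366 passed by the value table. Whether the list held more calls than that share was not tested. RAB22A, a small GTPase gene of early endosomes, averaged 7.89 ± 0.072 log2 without and 7.20 ± 0.052 log2 with doxycycline by the value table (SD, 2 arrays each). It fell by 0.69 log2 with a standard error of 0.089 (adjusted p = 0.0176, limma). It was the only member that passed when adjusted over the list alone as well. The pair of arrays that both accounts label alike, no dox 1 and dox 2, differed by -0.70 log2. This pair is part of the comparison that selected RAB22A, so its difference is no separate support. Without dox replicate 1 or 2 the call was lost (adjusted p = 0.0901 and 0.0612), as it was with scanner values scaled to the 75th percentile in the table's assignment (-0.89 log2, adjusted p = 0.0789). RAB22A differed by 0.007 log2 by the scanner labels, with a standard error of 0.46. Its only probe lay at chromosome 20, 56942283 to 56942342 (hg19). The list as a whole had a median of -0.032 log2 by the value table, with 19 of 31 members negative, and of 0.010 by the scanner labels, with 19 of 31 positive. Neither passed (adjusted p = 0.125 and 0.284, camera). HMX1, a homeobox gene, and HMGA2, a chromatin architectural gene, had the smallest p-values by the scanner labels, at 0.35 and 0.77 log2, without passing.

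**Figure D3:**
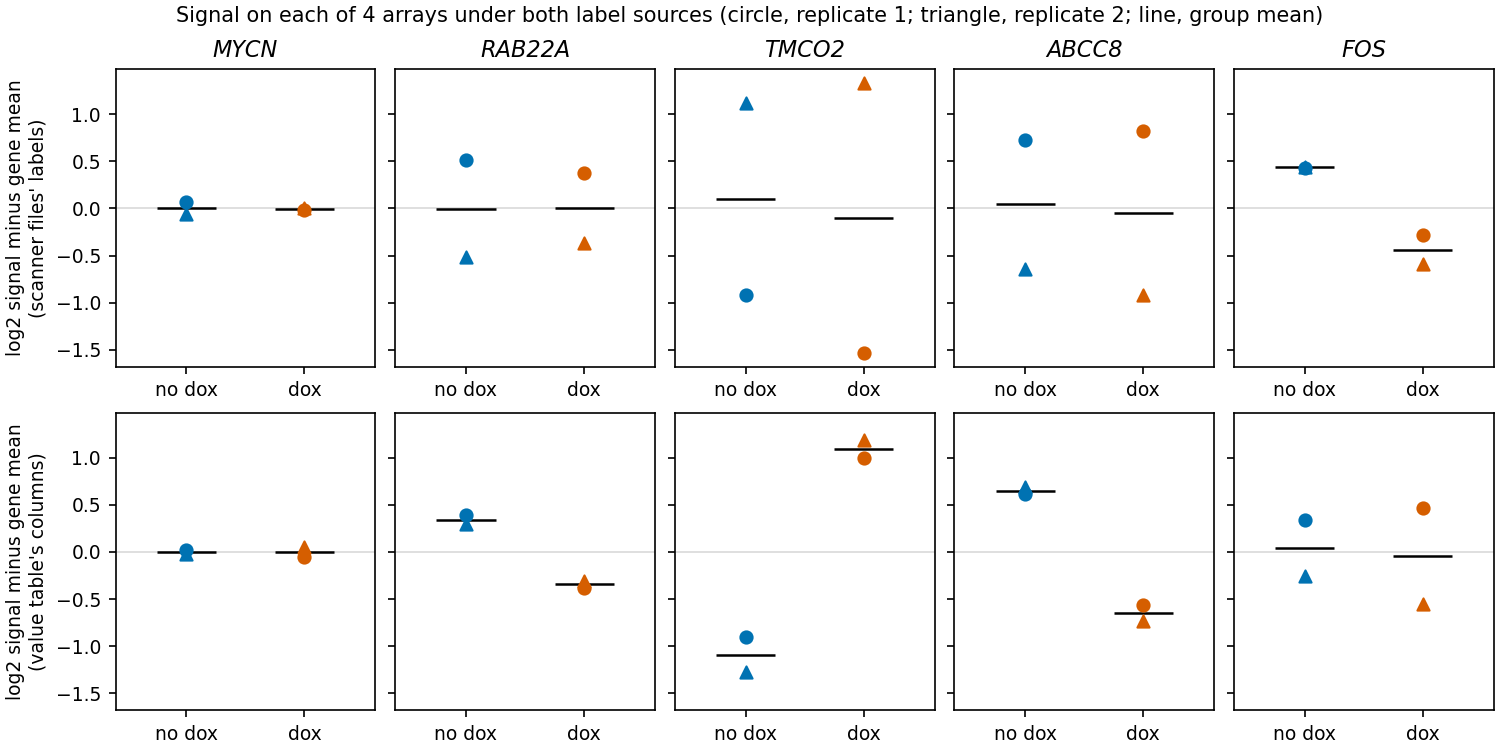
Log2 level on each of the 4 arrays, minus the gene's mean, for MYCN, RAB22A, TMCO2, ABCC8 and FOS; the top row uses scanner values under the scanner files' labels and the bottom row the deposited table's values under its own columns. MYCN spans 0.13 and 0.10 log2 over the 4 arrays, whereas RAB22A differs by -0.69 log2 between the groups only in the table's assignment.

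Fixed lists of genes were also tested as groups with limma's camera, 30 lists in each account. With an adjusted p below 0.05, 0 of 30 passed by the scanner labels, and no member of any list passed over all genes. In the table's account 2 lists passed, and 2 members of any list, RAB22A and SIX3. All genes had a median of -0.018 log2 by the scanner labels and 0.010 by the value table. Camera sets the moderated t-statistics of a list, not its log2 values, against those of all other genes. Its direction can therefore differ from the sign of a list's median or mean. By the scanner labels it pointed up for MYCN-repressed genes, S phase, catecholamine synthesis and the microRNA pathway, where median and mean were negative, for ribosome biogenesis, where the mean was negative, and for the integrated stress response and for glycolysis and hypoxia, where the median was. By the value table it pointed down for G2/M, mesenchymal and Schwann genes, where both were positive, for S phase, neuronal and unfolded protein response genes, where the mean was positive, and for immune markers, where the median was. It pointed up there for the microRNA pathway, where the median was negative. With a correlation estimated for each list no list passed, with a lowest adjusted p = 0.92 by the scanner labels and adjusted p = 0.951 by the value table. Without no dox replicate 1, the scanner labels gave 13 lists, 12 of them up, and the value table gave 0. Without dox replicate 2 the table gave 7 lists, all down. The members selected in each account have standard errors there of 0.09 to 0.32 log2 by the scanner labels and 0.08 to 0.27 by the value table. Apart from RAB22A and SIX3, none passed, and their lowest adjusted p was 0.599 by the scanner labels and 0.0563 by the value table (limma).

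Genes of cholesterol and fatty acid synthesis were lower as a group by the value table. Of 28 members 24 were negative, with a median of -0.12 log2 (adjusted p = 6.16e-04, camera; adjusted p = 0.951 with an estimated correlation). No single member passed. LSS, which encodes an enzyme of sterol synthesis, was at -0.24. Their median by the scanner labels was 0.017, with 16 members positive (adjusted p = 0.465, camera), MSMO1, another sterol enzyme gene, at 0.21 and ACACA, the first enzyme of fatty acid synthesis, at -0.28. Mitochondrially encoded genes were higher as a group by the value table, with a median of 0.26 log2 over 11 members (adjusted p = 0.0147, camera; adjusted p = 0.951 with an estimated correlation). MT-ND6, a complex I subunit, was at 0.73 and MT-CYB, of complex III, at 0.36, and no member passed. This median was 0.11 by the scanner labels (adjusted p = 0.161, camera), with MT-ND5 at 0.27 and MT-CO2 at 0.15. The call on this list was lost with scanner values scaled to the 75th percentile (mean 0.19 log2, adjusted p = 0.105) and without no dox replicate 1, no dox replicate 2 or dox replicate 2 (adjusted p = 0.0526, 0.0557 and 0.131). The call on cholesterol and fatty acid synthesis was lost with background-corrected scanner values (mean -0.11 log2, adjusted p = 0.163) and without no dox replicate 1 (adjusted p = 0.0526).

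The nuclear-encoded lists of the mitochondrion had small medians of opposite sign in the 2 accounts. Oxidative phosphorylation genes had a median of -0.061 log2 by the value table, 24 of 30 negative (adjusted p = 0.0631, camera), with NDUFA2 and COX4I1 at -0.14 each. Their median in the scanner account was 0.002 (adjusted p = 0.465), with the ATP synthase genes ATP5F1B at 0.14 and ATP5F1C at 0.18. Mitochondrial ribosome and translation genes stood at -0.054 by the value table and 0.049 by the scanner labels (adjusted p = 0.192 and 0.161, camera). MRPL15 was at -0.14 by the value table, MRPS27 at 0.22 by the scanner labels, and MRPL44 at 0.17 and 0.18. Glycolysis and hypoxia genes had medians of -0.039 and -0.008 (adjusted p = 0.216 and 0.458). LDHA and BNIP3 were at -0.15 and -0.13 by the value table. PFKL, a phosphofructokinase gene, was at 0.78 and PFKFB4 at -0.46 by the scanner labels.

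Lists tied to MYCN and growth did not pass in either account. Genes activated by MYC or MYCN had a median of -0.035 log2 by the value table, 30 of 45 negative, and of 0.033 by the scanner labels, 28 of 45 positive (adjusted p = 0.133 and 0.458, camera). MDM2, a ubiquitin ligase gene, was at 0.59 and PPAN at -0.17 by the value table, with ALK, a receptor kinase gene of neuroblastoma, at -0.53 and ABCC1 at -0.21 by the scanner labels. MYCN-repressed genes had medians of 0.017 and -0.029 (adjusted p = 0.922 and 0.76). TGFBI, which did not pass, had a bound of 1.16-fold higher by the value table, where TGM2 was at 0.23. By the scanner labels IL6 was at -0.26 and ITGA1 at 0.19. For ribosome biogenesis the medians were -0.046 and 0.017 (adjusted p = 0.125 and 0.568), with RRP1 at -0.16 and UTP20 at 0.16 by the value table, and POLR1A at -0.19 and NIP7 at 0.13 by the scanner labels. S phase and DNA replication genes stood at -0.017 and -0.020 (adjusted p = 0.81 and 0.721). CDC6, a replication licensing gene, was at 0.52 and UNG, the uracil glycosylase gene, at -0.40 by the value table, and DSCC1 was at 0.25 and POLE at -0.25 by the scanner labels. G2/M and mitosis genes stood at 0.006 and 0.045 (adjusted p = 0.935 and 0.125). ASPM and TTK were at 0.31 and 0.21 by the value table, and MKI67 and CENPA at -0.21 and 0.18 by the scanner labels. Histones had medians of 0.011 and 0.071 (adjusted p = 0.966 and 0.106), with H2BC8 at 0.16 and H2BC21 at 0.11 by the table, and H1-4 and H3C10 at 0.19 each by the scanner labels. In the latter account 15 of 17 histone genes were positive.

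Lists of neuroblastoma identity held 1 gene that passed. SIX3, a homeobox gene of the forebrain and eye, rose by 1.47 log2 with a standard error of 0.17 by the value table (adjusted p = 0.0114, limma). It was the only one of the 23 adrenergic transcription factors measured, over all genes and adjusted over the list alone. By the scanner labels SIX3 was at -0.40 log2 with a standard error of 0.78 (adjusted p = 0.97). In the table's assignment it did not pass with scanner values scaled to the 75th percentile or quantile normalized, at 1.55 log2 in each (adjusted p = 0.0951 and 0.121), and its adjusted p ran from 5.85e-04 to 0.121 across alternatives. The list had a median of 0.018 by the value table and -0.068 by the scanner labels (adjusted p = 0.81 and 0.458, camera), where GATA3 and TFAP2B were at -0.35 and -0.20. Mesenchymal neuroblastoma genes had medians of 0.014 and -0.054 (adjusted p = 0.949 and 0.677). WWTR1, which encodes TAZ, and IRF1 were at -0.44 and -0.34 by the table, and LOX and TBX18 at -0.45 and -0.41 by the scanner labels. Catecholamine synthesis and chromaffin markers stood at 0.029 and -0.021 (adjusted p = 0.81 and 0.741). GCH1, of tetrahydrobiopterin synthesis, and PNMT, which makes adrenaline, were at 0.41 and 0.31 by the table, and SCG3 and SLC18A1 at 0.19 and 0.20 by the scanner labels. Neuronal differentiation and neurite genes had medians of -0.005 and -0.074 (adjusted p = 0.89 and 0.465), with STMN4 at 0.44 and NTRK3 at 0.50 by the table, and SYT1 at -0.30 and NCAM1 at -0.19 by the scanner labels. For axon guidance and adhesion they were 0.031 and -0.078 (adjusted p = 0.896 and 0.514). SEMA3C and UNC5C were at 0.29 and 0.24 by the table. In the scanner account NRP2 was at -0.53 and EPHA7 had a bound of 1.2-fold lower, neither of them passing.

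Stress, death and signalling lists did not pass either. The immediate early and NF-kB genes had the lowest adjusted p by the scanner labels, shared with histones, at 0.106 in camera, with a median of -0.16 log2 and 15 of 21 negative. FOS and EGR1, transcription factors induced within minutes of growth factor signals, were at -0.87 and -0.91. In the value table the median was -0.022 (adjusted p = 0.896), CXCL2 was at 0.46 and NFKB2 at -0.22, and FOS and EGR1 were at -0.08 and -0.24, with standard errors of 0.34 and 0.35. Apoptosis regulators stood at -0.003 by the table and 0.020 by the scanner labels (adjusted p = 0.782 and 0.199), with CFLAR at 0.27 and BCL2L2 at -0.23 by the table, and APAF1, the apoptosome gene, at 0.57 and DIABLO at 0.29 by the scanner labels. Integrated stress response genes were at -0.043 and -0.011 (adjusted p = 0.0721 and 0.696). DDIT3, which encodes CHOP, was at 0.24 and SLC7A5 at -0.22 by the table, and ATF5 was at -0.17 and SESN2 at 0.41 by the scanner labels. The unfolded protein response list stood at -0.041 and 0.028 (adjusted p = 0.475 and 0.465). HYOU1, a chaperone gene, was at 0.79 and SDF2L1 at -0.17 by the table, and PDIA4 and EDEM1 were at 0.25 and 0.29 by the scanner labels. Interferon response genes had medians of 0.009 and -0.069 (adjusted p = 0.879 and 0.199), with MX2 and RIGI at 0.47 and 0.46 by the table and XAF1 and OASL at -0.61 and -0.41 by the scanner labels. TGF-beta and BMP response genes stood at 0.021 and -0.038 (adjusted p = 0.896 and 0.721). TGIF1, a repressor in the TGF-beta pathway, was at 0.65 and ID4 at 0.30 by the table, and TGIF2 was at -0.25 and BMPR2 at 0.36 by the scanner labels. Autophagy and lysosome genes were at -0.039 and 0.010 (adjusted p = 0.134 and 0.199), with MAP1LC3B and LAMP1 at -0.28 and -0.23 by the table, and ATG7 at 0.15 by the scanner labels. In the microRNA pathway the medians were -0.003 and -0.038 (adjusted p = 0.966 and 0.877). DICER1, which cuts microRNA precursors, was at 0.27 and TNRC6C at 0.23 by the table, and AGO3 was at -0.25 and LIN28A at 0.22 by the scanner labels. Adjusted over the list alone, HYOU1, CXCL2 and TGIF1 passed by the table, 1 in each of these lists.

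Markers of other cell types were measured to look for RNA of other cells, and none of these 4 lists passed. Schwann and glial markers had medians of 0.034 log2 by the value table and -0.033 by the scanner labels (adjusted p = 0.949 and 0.877, camera). NGFR, which did not pass, had a bound of 1.14-fold higher by the table. It was at -0.013 log2 with normexp and -0.081 with the strict filter, so its sign is not settled. ERBB3 was at -0.21 by the table, and SOX10 was at -0.08 and ERBB3 at 0.14 by the scanner labels. Fibroblast and stroma markers were at -0.056 and -0.037 (adjusted p = 0.328 and 0.79), with LUM and PDGFRB at -0.26 and -0.13 by the table, and DCN and PDGFRB at -0.13 and -0.07 by the scanner labels. Immune markers were at 0.026 and -0.020 (adjusted p = 0.782 and 0.697). MS4A1, of B cells, was at -0.62 by the table, and NKG7 and ITGAM at -0.78 and -0.55 by the scanner labels. Endothelial and epithelial markers stood at 0.039 and -0.15 (adjusted p = 0.896 and 0.161). VWF was at 1.00 and PECAM1 at -0.23 by the table, and PECAM1 was at -1.15 by the scanner labels, where EPCAM had the bound given above. Adjusted over the list alone, MS4A1 passed by the table and EPCAM by the scanner labels.

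**Figure D4:**
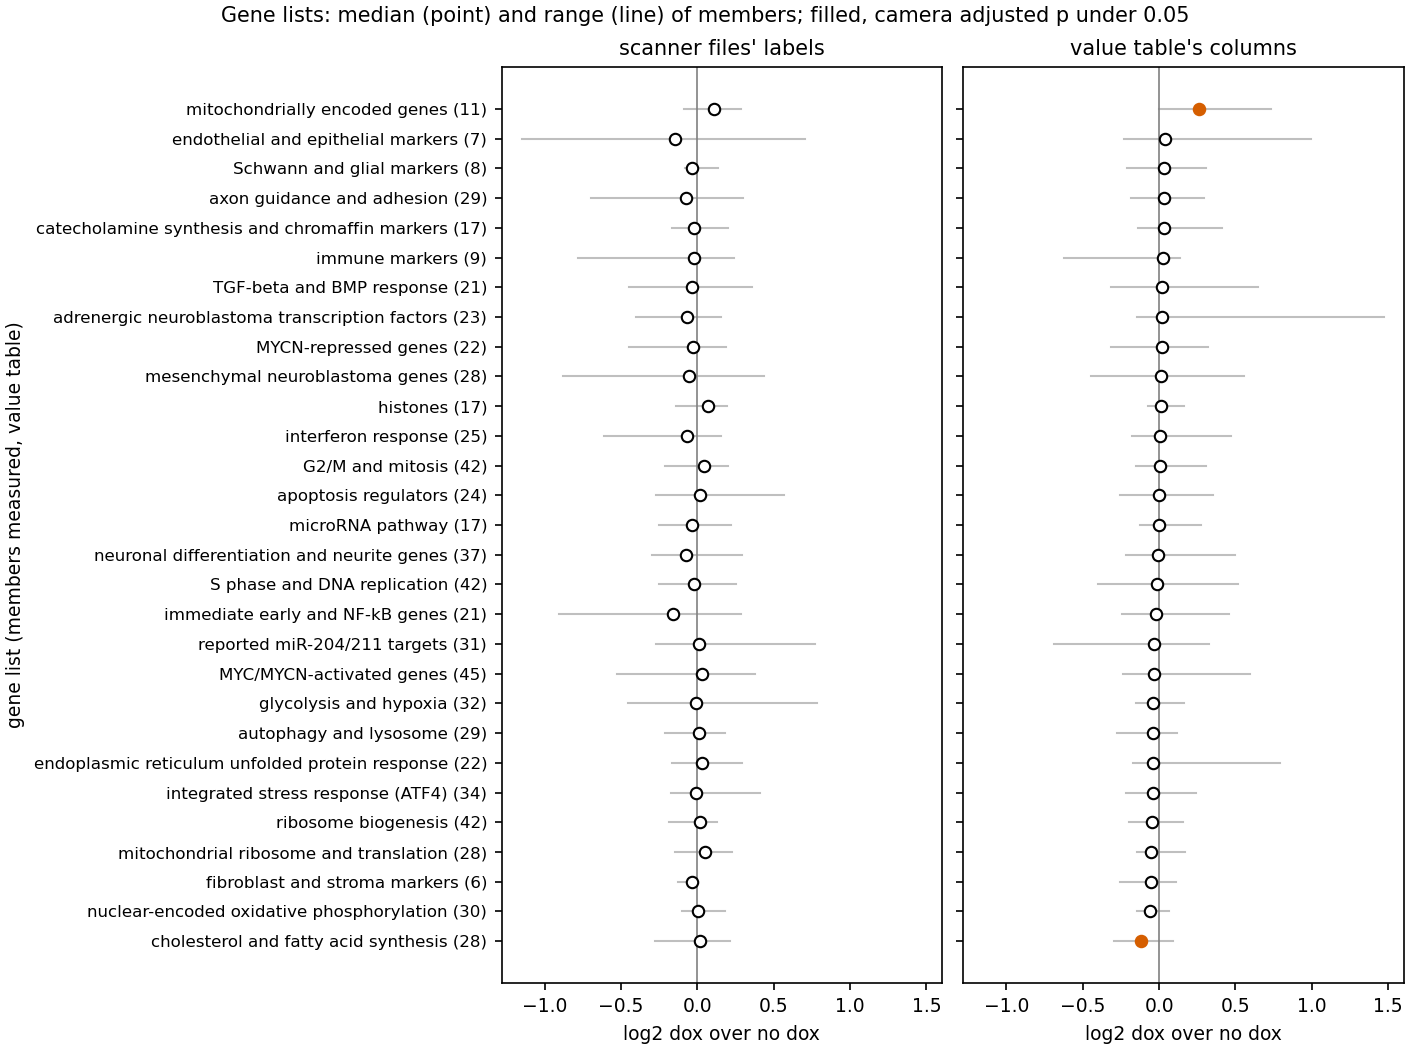
Median log2 change (point) and range over members (line) of the gene lists described in the text, with doxycycline over without, by the scanner files' labels and by the value table's columns; filled points mark an adjusted p below 0.05 in camera. Only cholesterol and fatty acid synthesis (median -0.12) and mitochondrially encoded genes (median 0.26) are filled, both by the value table.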

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

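All alternatives for the value table's account were chosen after seeing the data; those for the scanner labels were planned. By the scanner labels the count of genes was 0 in limma under every alternative except the value table, with 688 (normexp) to 2574 (replicate block) genes at an unadjusted p below 0.05. With the value table, which also exchanges 2 arrays, it was 549, and 267 at least 2-fold. Leaving out 1 array left an arm with 1 sample, assumed to vary like the other group, and gave 0 genes each time, with 1677 to 2562 at an unadjusted p below 0.05. MYCN was at 0.046 log2 with median scaling, -0.109 with quantile normalization and between -0.076 and 0.054 with 1 array left out. Of lists, 3 were called with normexp (all down), 2 with the trend and robust prior, 2 with the value table, and 0 to 13 with 1 array left out: 13 without no dox replicate 1 (12 up, 1 down) and 1 without dox replicate 1. By the value table's columns, 273 genes were called with scanner values at the 75th percentile (201 of the 549), 222 with quantile normalization (169 of the 549), 276 at adjusted p under 0.01, and 433 to 964 with 1 array left out, the highest without no dox replicate 2. At least 2-fold, 167 genes were called with normexp and 272 to 409 with 1 array left out, again highest without no dox replicate 2. Apart from the replicate block, the other alternatives stayed within 1.5 times of 549 and 267. MYCN was at 0.027 with quantile normalization and between -0.054 and 0.047 with 1 array left out. RAB22A was at -0.887 with the 75th percentile (adjusted p = 0.0789), -0.898 with quantile normalization (adjusted p = 0.0912) and -0.737 to -0.635 with 1 array left out, lost without dox replicate 1 or 2; its adjusted p ran from 0.0115 to 0.0912 over all alternatives. Lists called were 1 with normexp, 0 with an estimated correlation, and 0 to 7 with 1 array left out: 0 without no dox replicate 1, 1 without no dox replicate 2 and 7 without dox replicate 2. The cause of these differences was not tested, apart from the exchange of arrays.

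Replicate numbers give no stated pairing. As a paired check, the deviations of the replicates correlated at 0.40 over genes by the scanner labels and at 0.152 by the value table. Because 2 arrays are exchanged, the replicate number in each account is the group of the other account. By the scanner labels, the table's comparison is one of replicate 2 against replicate 1. This check and the replicate block therefore cannot tell pairing from the other account's group difference. With the replicate block, 0 genes were called by the scanner labels and 837 by the value table, 732 higher and 105 lower, which held all 549.

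Of the named genes of the scanner account, 23 changed sign with the value table, which differs in both its values and its assignment: TRPM3 -0.02, MKI67 0.091, SOX10 0.042, ERBB3 -0.212, TGIF2 0.088, TIGAR 0.079, GATA3 0.01, NRP2 0.165, EDEM1 -0.055, DCN 0.11, PFKL -0.135, PFKFB4 0.128, NKG7 0.052, LOX 0.017, TBX18 0.006, LIN28A -0.098, SYT1 0.005, ATP5F1C -0.094, MIR940 -0.19, FAM222B -0.085, LYNX1 -0.063, LINC02082 -0.114 and FLJ39095 0.056. With the mean over probes TRPM3 was at -0.144, ERBB3 at -0.05 and PDGFRB at 0.122, and EPHA7 was at 0.017 with normexp. By the value table, TRPM3 was at 0.038 with the mean over probes, and without probes that hold the TCTCCC stretch ANO7 was at -0.12, LINC00842 at -0.139, ZAN at 0.423, TUNAR at 0.05 and CFLAR at -0.051, then read by another probe. NGFR was at -0.013 with normexp and -0.081 with the strict filter. With 1 array left out, TRPM3 ran from -0.02 to 0.045, ERBB3 from -0.188 to 0.458, DCN from -0.297 to 0.045 and PDGFRB from -0.203 to 0.055 by the scanner labels, and TGM2 from -0.073 to 0.262 by the value table. Otherwise the named genes and alternatives gave 52 values by the value table that lost their call and 20 that gained one, with the same direction. No scaling moved the median of all genes by more than 0.1 log2. The planned seed site shift was not run, since no 3' UTR sequences were at hand. Probes not well above background limit what can be said of dim genes, which have only bounds.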

Other observations

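Of the tests in this part, those of probe-specific signal and of a brighter array were written down before their results were seen; all others were chosen afterwards.

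The pair of arrays that both sources label alike, no dox 1 and dox 2, gives 1 array against 1 and so no test. Genes and lists picked by their values in either account were picked partly on this pair, so it gives them no separate support. In the scanner values FOS and EGR1 differed by -1.02 and -1.28 log2 in this pair, and in the deposited table by -0.89 and -1.10. RAB22A differed by -0.88 and -0.70, and MYCN by -0.06 and 0.02. In the table's values the median over mitochondrially encoded genes was 0.33 log2 in this pair, and that over cholesterol and fatty acid synthesis genes was -0.16. MYCNOS, the antisense neighbour of MYCN, was measured by 2 probes. They differed by 0.046 and 0.057 log2 by the scanner labels and by -0.083 and -0.063 by the value table, with adjusted p from 0.891 to 0.978 in limma.

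The first pattern is the match of 2 columns of the value table with each other's scanner array. An exchange of 2 arrays between the sources predicts this, and the lower of the 2 correlations was 0.905. The authors' normalization is argued against, since the remaining columns matched their own arrays at 0.916 or more. Which source is right stays open: of "the scanner files carry the wrong labels" nothing decides, because the array had 0 probes of the induced microRNA. In scanner values the table's assignment called 273 genes and each of the other 2 splits called 0, but 3 splits are too few to reach a share under 0.05, and slide column follows that assignment.

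In the second pattern, the genes called by the value table's columns, 70 had another measured probe, and the other probes moved by 1.0% of the called probes' median (95% interval -1.9 to 4.4%), which is consistent with probe-specific signal; change in single transcript forms is also open and was not tested. The called probes were also selected by their change, so a smaller change of the others was in part built in. Over 5986 genes with another probe, tested and other probes correlated at 0.043 by the value table and 0.034 by the scanner labels. Most of these genes passed in neither account, and probes of unchanged genes need not correlate. These values therefore cannot tell whether the disagreement was particular to the called genes. A brighter array lifting probes near background is argued against as the whole cause. Of the genes called higher, 81.2% stayed when only probes well above background on all arrays were used. From 66.3% to 77.9% of spots per array passed that flag, so the filter does not take out all dim probes. The array with the highest median signal is a dox array in this account. The authors' normalization is argued against as the source of the differences, since in scanner values at the 75th percentile 548 of 549 kept their direction and the median change was 155.7% of that in the table (1.54 against 0.99 log2, median standard errors 0.15 and 0.10). The number of calls does depend on the processing: 36.6% (201) were still called, and the 348 lost had a median of 1.29 log2 against 0.88 in the table. Their median standard error rose from 0.11 to 0.18. With normexp, 422 of the 549 were called. These scanner settings also differ in background handling, so the part of the authors' normalization in the lost calls was not separated. Probes with the stretch TCTCCC, which matches the leader of the transcription primer, were 7.5% of the called and 2.7% of the other probes (odds ratio 2.91, two-sided Fisher's exact p = 1.4e-08), too few to be the whole cause.

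The last test asked whether the induced microRNA lowers transcripts with its seed match, a hypothesis that could be read only from the 60-base probes and not from whole 3' UTRs. Among 11963 heptamers each held by at least 20 probes of coding genes, the seed match ranked 32.5% from the lowest mean change by the value table (86 probes), and among 11947 such heptamers 55.6% by the scanner labels (85 probes). Neither rank lies in the lowest 5%, and with so few probes and unsettled labels the hypothesis stays open.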
